A study of Mus musculus with 12 samples.

How the data were processed

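The 12 samples were pools of sorted mouse CD4 T cells, each hybridized to an Affymetrix mouse genome array after amplification of 20 ng of total RNA, per the labels. The deposited values are log2 signals per probe set, which the authors made with GCRMA, a background adjustment from probe sequence with quantile normalization and a summary over probes. The submitters' processing notes give no version and do not say which arrays were normalized together. The value table held 45101 probe sets, and the probe annotation gave 34958 of them 1 gene symbol. Probe sets with several symbols (932) or none (9211) were left out of the comparisons of genes. Scanner files and detection calls were not available.

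A probe set was kept if it reached log2 5 on at least 2 arrays, and the kept probe set with the highest mean over all arrays stood for its gene, which left 9892 genes. All 12 arrays entered 1 fit of 5 groups in limma 3.58.1 (R 4.3.3), because 3 groups had 2 arrays each, with 7 residual degrees of freedom. The 6 comparisons used 2-sided moderated tests, Benjamini-Hochberg adjustment over all genes tested, and an adjusted p under 0.05. Of 24 gene lists written in advance, those with at least 5 measured genes, 20 in number and 1 of them the list of gate genes, were tested against the other genes with camera at a preset inter-gene correlation of 0.01. With an estimated correlation camera called 0 of these lists in every comparison, with 3, 2, 4, 3, 5 and 5 at an unadjusted p under 0.05. The rotation test fry, which asks whether the genes of a list move 1 way, called 5, 0, 6, 4, 11 and 12. With the batch term described below, fry called 13, 7, 12, 8, 16 and 16, and camera with an estimated correlation again called 0. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

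The groups, comparisons, tests, lists, first alternatives and rule for named genes were fixed before the data were examined. For Venus-high against Venus-low Tfh, the rule took the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between the groups, and for each other comparison the 5 largest. If fewer passed, all that passed were named, and if fewer than 5 passed, the 10 with the smallest unadjusted p, as not passing. For each list described it took up to 4 members with the largest change among those past the threshold, or the 2 with the smallest p where none passed, as values. Not all list members taken this way are printed below. S1pr2 and the gate genes tested were named whatever their values. B cell, CD8, NK, gamma delta T and myeloid cell marker genes outside this rule are named for their levels and were chosen after their values were seen. Alternatives changed the filter, the floor, the normalization, the variance model, the arrays in the fit, a block for the replicate number, the pool size, array weights, the choice of probe set, the fold, and each array in turn.

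Hierarchical clustering of the arrays' quantiles was cut into 3 clusters, a number set by choice, and these are called batches. The 75% quantiles of their arrays were 8.50 to 8.55, 8.68 to 8.76 and 9.39 to 9.42 in batches 1, 2 and 3. Batch as a fixed term, which left 5 residual degrees of freedom, and batch as a random block were alternatives chosen after seeing the data. Displaced probe sets were found in a fit of group and batch, as those whose batch 2 effect differed from both other batches by more than 3 log2 units in 1 direction, a threshold chosen after seeing the data. With thresholds of 2, 3 and 4, the fit without a batch term called 160, 153 and 150 genes between the Tfh groups, and with it 1715, 1718 and 1701. Smaller displacements stay undetected, and the values of these probe sets were not moved or corrected.

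The fits were tested on simulated data for Venus-high against Venus-low Tfh, made from the batch effects, group means and residual spread of the 9892 genes with the difference set to 0 except in the changed genes. Of 100 genes changed by 1 log2 unit, the fit without the batch term recovered 6% and the fit with it 64%. Of 100 genes changed by 3 units they recovered 64% and 90%, with 1 and 11 false calls. The simulated arrays followed the model with the batch term, so the higher recovery of that fit was built in. It does not show which fit suits the real arrays. Camera, with the batch term and the preset correlation, called the 1 list that had been shifted and 0 of the other lists of the 20 tested. The simulated genes varied independently, so this does not test camera where genes of a list vary together, nor the fit without the batch term.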

Results

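Gene expression was measured on 12 arrays, each holding the pooled cells of 2 to 6 mice. The mice carried a Venus fluorescence reporter at S1pr2, the gene of a sphingosine-1-phosphate receptor, and were studied 10 days after immunization with chicken gamma globulin. Follicular helper T cells (Tfh), which help B cells in germinal centres, had been sorted from lymph nodes as Venus-high (3 arrays) and Venus-low (3 arrays). The other lymph node groups were CXCR5+ T helper (Th) cells with intermediate PD1 (2 arrays) and Th cells with low CXCR5 and low PD1 (2 arrays). Naive CD4 T cells came from spleen (2 arrays), and the labels leave open whether their donors had been immunized. The number of arrays limits the precision. All differences are log2, first group minus second, with the SE. Unless the batch term is named, SE and adjusted p are from the fit without it, so they include spread between batches. For Venus-high against Venus-low Tfh the median SE over genes was 0.40 without the batch term and 0.15 with it. Where a group lay below log2 5 on every array, that level was the floor for a lower bound of the fold.

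By their quantiles the arrays were divided into 3 batches that the labels do not name. Part of the values of 1 batch were out of place. Batch 1 held 3 arrays, batch 2 held 4 and batch 3 held 5, and Venus-high and Venus-low Tfh were the groups with an array in each. In batch 2, 3289 probe sets lay more than 3 log2 units from both other batches in 1 direction, against 542 in batch 1 and 233 in batch 3. The 7 hybridization control probe sets, for transcripts added to every sample, read at least 11.71 in batch 1 and 11.74 in batch 3, but at most 2.61 in batch 2. Of 9010 genes with several probe sets, 550 had both an upward and a downward displaced probe set, where 60.6 would follow from independence.

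In 486 genes with 1 probe set displaced each way, the Venus-high minus Venus-low difference of the downward probe set correlated across genes by 0.752 between batches 1 and 3 and by 0.184 between batches 2 and 3. The value was 0.715 when batch 2 was read from the gene's upward probe set, and genes are not independent replicates. Displaced probe sets measured 507 of the 9892 tested genes, among them the list members Top2a, Tox2, Prf1, Capg, Itga4, Ccr9, Socs1, Dusp5, Tnfaip3, Pax5 and Zbtb46, which stay in the list counts and are not described. No other gene named here was measured by one. Each count of genes is therefore followed by the count without the displaced probe sets and the count with batch as a term, both chosen after seeing the data.

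**Figure D1:**
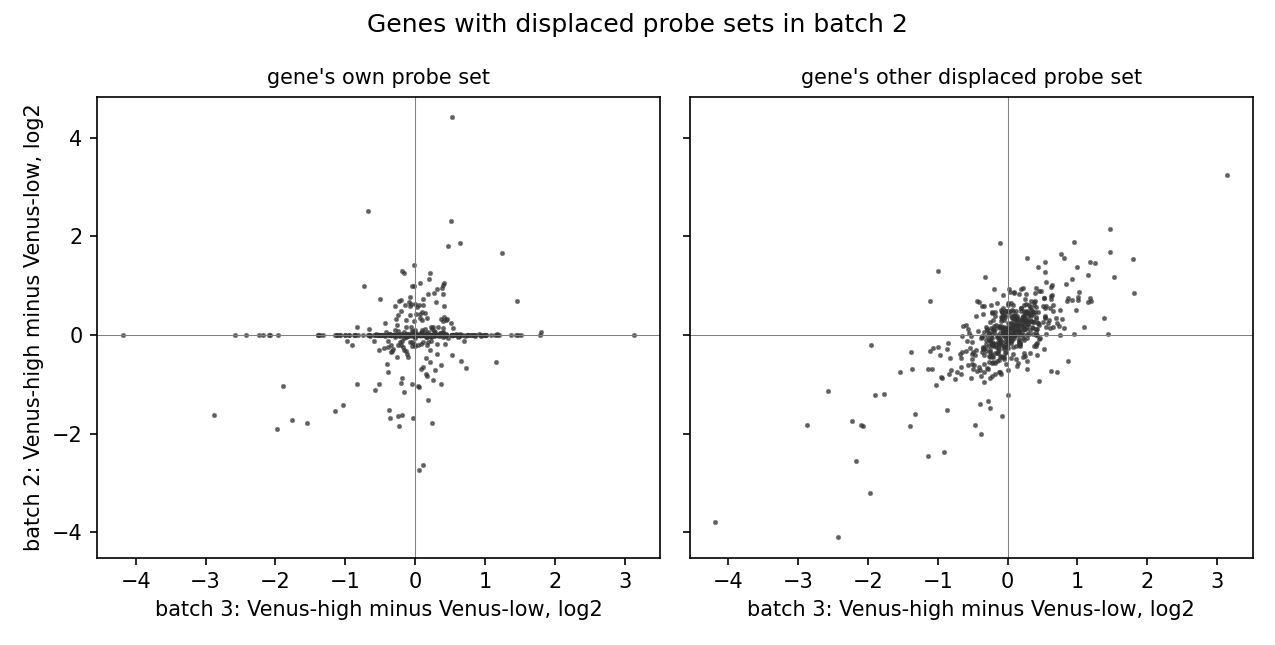
Venus-high minus Venus-low Tfh log2 difference in batch 3 (horizontal) against batch 2 (vertical), 1 point per gene, for the 486 genes with 1 probe set displaced down and 1 displaced up in batch 2. The downward probe set gives batch 3 in both panels and batch 2 on the left, where many values sit at the floor of the array, and the upward probe set gives batch 2 on the right, with correlations of 0.184 and 0.715.

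S1pr2 itself, whose reporter had been used for the sort, is no finding between the Tfh groups and served as a check of the labels. Its level was 12.89 ± 0.27 (SD, n = 3) in Venus-high Tfh, 10.25 ± 0.41 (SD, n = 3) in Venus-low Tfh, 9.31 ± 0.03 (SD, n = 2) in PD1-intermediate, 7.41 ± 0.25 (SD, n = 2) in PD1-low and 6.34 ± 0.79 (SD, n = 2) in naive cells. Between the Tfh groups S1pr2 rose by 2.64 ± 0.34 (adjusted p = 0.0105), and by 2.41, 2.72 and 2.78 within batches 1, 2 and 3. The call was lost on the 6 arrays alone (adjusted p = 0.0849), with the mean of all probe sets of a gene (adjusted p = 0.0631) and without Venus-low replicate 2 (adjusted p = 0.0518), within a range of adjusted p from 2.51e-05 to 0.0849 over all alternatives. The other gate genes differed by 0.73 ± 0.38 (adjusted p = 0.688) for Cxcr5, 0.70 ± 0.46 (adjusted p = 0.875) for Pdcd1, -0.08 ± 0.59 (adjusted p = 1.00) for Cd44 and 0.00 ± 0.31 (adjusted p = 1.00) for Cd4.

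**Figure D2:**
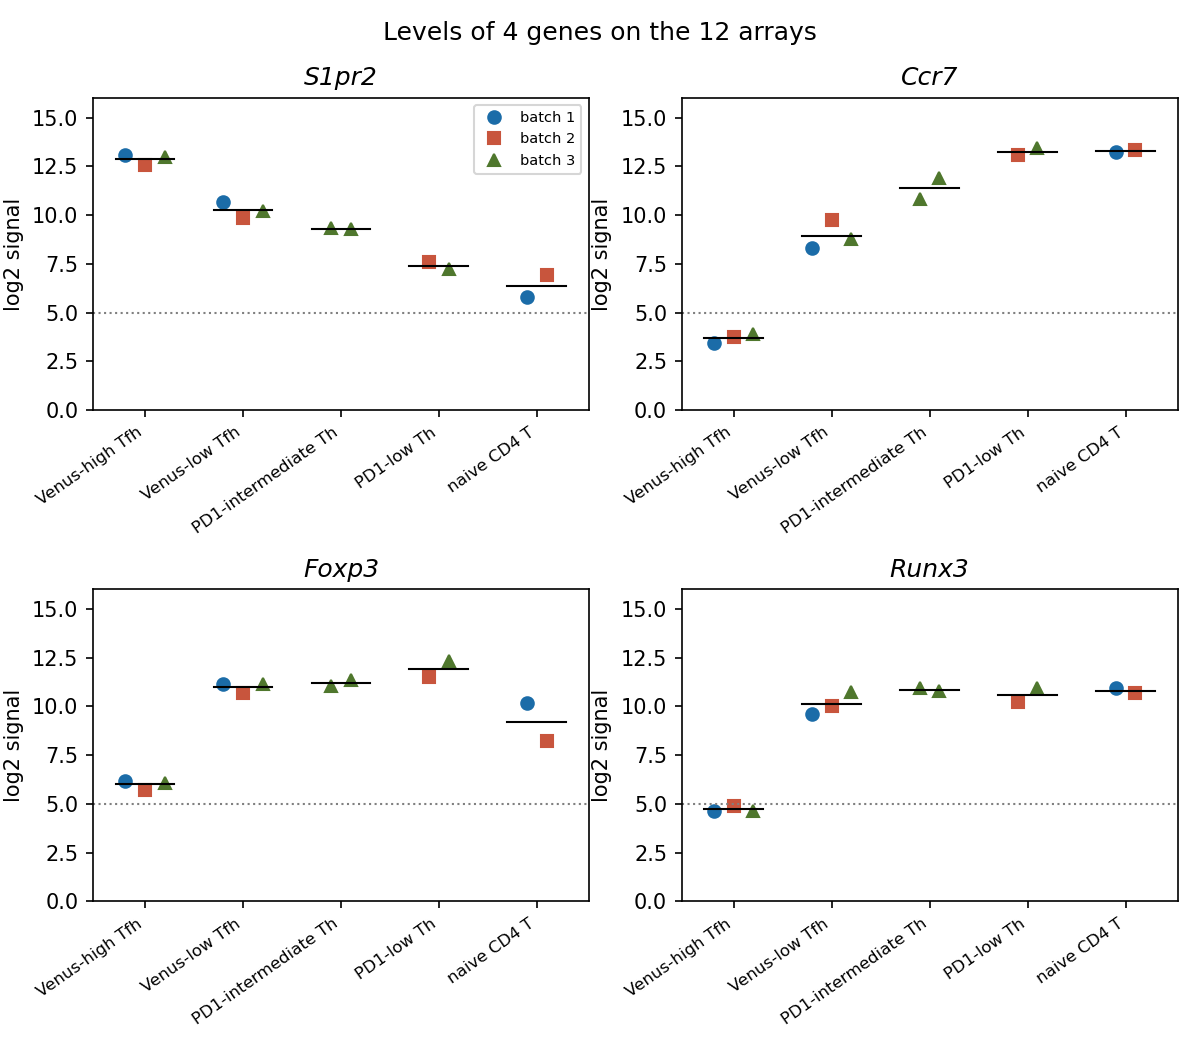
Log2 signal of S1pr2, Ccr7, Foxp3 and Runx3 on each of the 12 arrays by group, 1 point per array, with the batch as shape and colour, the group mean as a black line and log2 5 as a dotted line. All 3 Venus-high arrays sit above the Venus-low arrays for S1pr2, and below them for Ccr7, Foxp3 and Runx3.

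The comparison of Venus-high with Venus-low Tfh asked how Tfh cells that express the S1pr2 reporter strongly differ from those that express it weakly. Ccr7, the chemokine receptor that guides T cells to the T zone, fell by 5.24 ± 0.41, at least 15.4-fold (adjusted p = 0.00127, n = 3 and 3), and Foxp3, the regulator of regulatory T cells, fell by 5.003 ± 0.46 (adjusted p = 0.00183). Runx3, a transcription factor of cytotoxic and Th1 cells, was at least 34.5-fold lower (adjusted p = 5.71e-04), and Nkg7, a gene of cytotoxic granules, at least 21.8-fold lower (adjusted p = 0.0269). Apoe, which encodes an apolipoprotein, was at least 17.9-fold higher (adjusted p = 0.010005), and Mef2b, a transcription factor of germinal centre B cells, at least 6.45-fold higher (adjusted p = 0.00590).

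In the T zone homing and egress receptor list, 0 of 10 measured genes rose and 3 fell, 0 and 8 adjusted over the list alone, and 1 and 8 with the batch term (list lower in camera, adjusted p = 3.50e-12, and adjusted p = 0.128 with an estimated correlation). Besides Ccr7, Il7r, the receptor of the survival cytokine interleukin 7, fell by 3.27 ± 0.38, and Itgb7, an integrin subunit, fell by 1.05 ± 0.17. In the naive and quiescence list, 0 of 17 measured genes rose and 3 fell, 0 and 6 adjusted over the list alone, and 2 and 7 with the batch term (list lower in camera, adjusted p = 1.66e-04, and adjusted p = 0.288 with an estimated correlation). Actn1 fell by 1.77 ± 0.27. In the regulatory T cell list, 3 of 14 measured genes fell, 5 adjusted over the list alone and 7 with the batch term (list lower in camera, adjusted p = 6.95e-07, and adjusted p = 0.288 with an estimated correlation). Besides Foxp3, Ikzf4 was at least 10.9-fold lower and Gpr83 fell by 3.99 ± 0.57. In the Th1 list, 0 of 13 measured genes rose and 2 fell, 0 and 3 adjusted over the list alone, and 1 and 4 with the batch term (list lower in camera, adjusted p = 5.70e-05, and adjusted p = 0.288 with an estimated correlation). Besides Runx3, Il18rap fell by 5.21 ± 0.93. In the Th17 list, 1 of 7 measured genes fell, 4 adjusted over the list alone and 4 with the batch term (list lower in camera, adjusted p = 5.70e-05, and adjusted p = 0.278 with an estimated correlation). Tmem176a, a membrane protein gene, fell by 2.27 ± 0.35. In the IL-2 and STAT5 response list, 1 of 16 measured genes fell, 2 adjusted over the list alone and 4 with the batch term (list lower in camera, adjusted p = 2.75e-04, and adjusted p = 0.331 with an estimated correlation). Cish, an inhibitor of cytokine signalling, was at least 6.57-fold lower. In the CD8, NK and gamma delta T cell list, 1 of 8 measured genes fell, 4 adjusted over the list alone and 3 with the batch term (list lower in camera, adjusted p = 1.72e-05, and adjusted p = 0.220 with an estimated correlation). Of its other members, Klrd1 differed by -2.61 ± 0.59 (adjusted p = 0.0907) and Klrc1 by -2.91 ± 0.78 (adjusted p = 0.153), while Cd8a and Ncr1 stayed below log2 5 on every array.

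In the cell cycle list, 2 of 31 measured genes fell, 23 adjusted over the list alone and 23 with the batch term (list lower in camera, adjusted p = 1.68e-23, and adjusted p = 0.220 with an estimated correlation). Cdc20, an activator of the complex that ends mitosis, fell by 1.86 ± 0.28, and Mcm3, a subunit of the replicative helicase, fell by 1.47 ± 0.28. In the Tfh programme list, 0 of 22 measured genes passed the test in limma, while 4 were higher and 0 lower at an unadjusted p under 0.05, 1 and 0 passed adjusted over the list alone and 6 rose and 0 fell with the batch term (list higher in camera, adjusted p = 0.00128, and adjusted p = 0.472 with an estimated correlation). Ascl2, a transcription factor of Tfh cells, differed by 2.98 ± 0.59 (adjusted p = 0.0543) and Rgs16 by 1.92 ± 0.52 (adjusted p = 0.156). In the germinal centre B cell and plasma cell list, 2 of 5 measured genes rose, 2 adjusted over the list alone and 2 with the batch term (list higher in camera, adjusted p = 0.00336, and adjusted p = 0.278 with an estimated correlation, and adjusted p = 0.130 with the batch term). Its risers were Mef2b and S1pr2, the gene of the sort. Without the gate gene S1pr2, left out after seeing the data, 1 of 4, Mef2b, rose (camera, adjusted p = 0.133, and adjusted p = 0.510 with an estimated correlation). In the B cell list, 1 of 8 measured genes fell, 1 adjusted over the list alone and 2 with the batch term (camera, adjusted p = 0.700). Cd72 fell by 1.81 ± 0.35, and the B cell genes Cd79a and Ms4a1 stayed below log2 5 on every array.

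Among the other large rises, Apoc4 was at least 12.5-fold higher, Il13ra1 at least 13.9-fold, Mcf2l at least 9.42-fold, Klrb1a at least 6.93-fold, Adamtsl2 at least 4.55-fold and Nfe2 at least 2.37-fold. Fam71b rose by 4.95 ± 0.40 and Ntf5 rose by 4.66 ± 0.71. Among the other large falls, Itgb3 was at least 12.2-fold lower, Ctla2a at least 11.2-fold, Aunip at least 6.84-fold and Adam8 at least 5.45-fold. In all, limma called 130 genes for this comparison, 43 higher and 87 lower in Venus-high Tfh, 153 without the displaced probe sets, and 1671 with the batch term, 739 higher and 932 lower. The median of all genes shifted by 0.02, and by 0.02 with the batch term. Within batches 1, 2 and 3, Ccr7 differed by -4.85, -6.01 and -4.86, Foxp3 by -4.96, -4.98 and -5.07 and Runx3 by -4.95, -5.12 and -6.10. Tfh arrays of equal replicate number were also those of equal batch. The deviations of these pairs from their group means correlated across genes by 0.914, 0.945 and 0.915. For the PD1-low group, batch rather than number went with such correlation. Venus-high array 2 correlated by 0.861 with PD1-low array 1 of its batch. The value of -0.861 with PD1-low array 2 is no second result, since the deviations of 2 arrays from their mean are mirror images. Both PD1-intermediate arrays were in batch 3, so their deviations could not show a batch. They correlated by 0.055 and -0.055 with Venus-high array 3. The 6 Tfh arrays alone gave 1001 genes with the pair as a block and 4 without it. The count was 84 without Venus-high replicate 1, 72 without Venus-high replicate 2, 68 without Venus-high replicate 3, 33 without Venus-low replicate 2 and 61 without Venus-low replicate 3.

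Venus-low Tfh were compared with PD1-intermediate cells to ask what separates these CXCR5+ populations. Ascl2, a transcription factor of Tfh cells, was at least 19.6-fold higher in Venus-low Tfh (adjusted p = 0.00921, n = 3 and 2). Il4, a cytokine of Tfh and Th2 cells, rose by 4.69 ± 0.74 (adjusted p = 0.0351), and Rgs16 rose by 4.52 ± 0.58. Lgals3, a galectin gene, was at least 56.5-fold higher, and Gal, the gene of the neuropeptide galanin, was at least 13.7-fold higher. Acvrl1, a receptor of the TGF-beta family, was at least 10.1-fold lower (adjusted p = 2.85e-04).

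In the Tfh programme list, 3 of 22 measured genes rose, 4 adjusted over the list alone and 7 with the batch term (list higher in camera, adjusted p = 9.51e-06, and adjusted p = 0.432 with an estimated correlation). In the cell cycle list, 1 of 31 measured genes rose, 1 adjusted over the list alone and 12 with the batch term (list higher in camera, adjusted p = 4.16e-22, and adjusted p = 0.287 with an estimated correlation). Cdc20 rose by 2.50 ± 0.31. In the glycolysis list, 0 of 15 measured genes passed the test in limma, while 5 were higher and 1 lower at an unadjusted p under 0.05, 1 and 0 passed adjusted over the list alone and 3 rose and 0 fell with the batch term (list higher in camera, adjusted p = 1.03e-05, and adjusted p = 0.414 with an estimated correlation). In the naive and quiescence list, 0 of 17 measured genes passed the test in limma, while 0 were higher and 8 lower at an unadjusted p under 0.05, 0 and 4 passed adjusted over the list alone and 0 rose and 3 fell with the batch term (list lower in camera, adjusted p = 8.22e-05, and adjusted p = 0.414 with an estimated correlation). In the T cell receptor and costimulation response list, 1 of 24 measured genes rose, 1 adjusted over the list alone and 5 with the batch term (list higher in camera, adjusted p = 0.0462, and adjusted p = 0.900 with an estimated correlation, median difference -0.18). Nr4a2, an early gene of receptor signalling, was at least 5.76-fold higher. In the germinal centre B cell and plasma cell list, 0 of 5 measured genes passed the test in limma, while 2 were higher and 0 lower at an unadjusted p under 0.05, 0 and 0 passed adjusted over the list alone and 2 rose and 0 fell with the batch term (list higher in camera, adjusted p = 9.31e-05, and adjusted p = 0.287 with an estimated correlation). S1pr2 differed by 0.94 ± 0.38 (adjusted p = 0.447). Without S1pr2, left out after seeing the data, camera gave adjusted p = 0.00179 for the remaining 4 genes, and adjusted p = 0.393 with an estimated correlation. Nrbp2 was at least 27.0-fold higher and Cxxc5 at least 18.7-fold. Further falls were those of Cdh13, at least 8.39-fold, of Adcy6, at least 13.9-fold, of B430306N03Rik, at least 6.82-fold, and of Lypd6b, at least 2.92-fold. In all, limma called 56 genes for this comparison, 35 higher and 21 lower in Venus-low Tfh, 72 without the displaced probe sets, and 631 with the batch term, 393 higher and 238 lower. The median of all genes shifted by -0.40, and by -0.01 with the batch term. Both PD1-intermediate arrays were in batch 3, so that batch alone held both groups, with a difference of 7.92 for Ascl2. The count was 28 without Venus-low replicate 2, 8 without Venus-low replicate 3, 8 without PD1-intermediate replicate 1 and 5 without PD1-intermediate replicate 2.

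PD1-intermediate and PD1-low cells differ by the gates for CXCR5 and PD1, and were compared for what goes with them. Il21, the main cytokine of Tfh cells, was at least 80.9-fold higher in PD1-intermediate cells (adjusted p = 2.25e-04, n = 2 and 2). Il1r2, a decoy receptor of interleukin 1, was at least 86.7-fold higher (adjusted p = 3.13e-05), and Il1r1, the signalling receptor, was at least 52.4-fold higher (adjusted p = 0.00493). Cdk1, the kinase that starts mitosis, rose by 5.42 ± 0.81 (adjusted p = 0.00649). Igfbp4, a gene of resting naive T cells, fell by 8.40 ± 1.08 (adjusted p = 0.00302).

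In the Tfh programme list, 10 of 22 measured genes rose, 15 adjusted over the list alone and 15 with the batch term (list higher in camera, adjusted p = 6.22e-11, and adjusted p = 0.212 with an estimated correlation). Cebpa was at least 115-fold higher, Il4 was at least 3.08-fold higher and Gpm6b rose by 3.40 ± 0.70. In the cell cycle list, 12 of 31 measured genes rose, 26 adjusted over the list alone and 23 with the batch term (list higher in camera, adjusted p = 6.87e-20, and adjusted p = 0.190 with an estimated correlation). Tpx2 rose by 5.39 ± 0.67, Cdc6 rose by 4.95 ± 0.97 and Bub1 was at least 13.5-fold higher. In the Th17 list, 5 of 7 measured genes rose, 6 adjusted over the list alone and 5 with the batch term (list higher in camera, adjusted p = 1.35e-06, and adjusted p = 0.190 with an estimated correlation). Rora, a transcription factor of Th17 cells, rose by 3.82 ± 0.65, and Ccr6, a chemokine receptor, rose by 5.36 ± 1.18. In the inflammatory homing receptor list, 2 of 13 measured genes rose, 5 adjusted over the list alone and 6 with the batch term (list higher in camera, adjusted p = 4.69e-04, and adjusted p = 0.351 with an estimated correlation). Cxcr6 rose by 5.29 ± 1.11. In the inhibitory receptor list, 3 of 11 measured genes rose, 4 adjusted over the list alone and 4 with the batch term (list higher in camera, adjusted p = 1.02e-04, and adjusted p = 0.351 with an estimated correlation). Lag3 rose by 5.84 ± 0.76 and Cd160 rose by 3.12 ± 0.58, while the third riser, Pdcd1, was a gate gene. Without the gate gene Pdcd1, left out after seeing the data, 2 of 10 rose (camera, adjusted p = 0.00193, and adjusted p = 0.542 with an estimated correlation). In the naive and quiescence list, 0 of 17 measured genes rose and 1 fell, 0 and 4 adjusted over the list alone, and 1 and 5 with the batch term (list lower in camera, adjusted p = 3.73e-07, and adjusted p = 0.190 with an estimated correlation). The B cell gene Cd22 was at least 26.4-fold higher, and the plasma cell gene Sdc1 was at least 4.19-fold higher. Nebl was at least 125-fold higher and Trpm6 at least 50.3-fold, while Pdlim4 was at least 96.0-fold lower, Ampd1 at least 26.2-fold, Amigo2 at least 28.1-fold and Gpr34 at least 20.5-fold.

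In all, limma called 397 genes for this comparison, 304 higher and 93 lower in PD1-intermediate cells, 443 without the displaced probe sets, and 1266 with the batch term, 800 higher and 466 lower. The median of all genes shifted by 0.29, and by 0.00 with the batch term. Batch 3 alone held both groups, with a difference of 8.66 for Il21 and 4.15 for Cdk1. The count was 137 without PD1-intermediate replicate 1, 177 without PD1-intermediate replicate 2 and 180 without PD1-low replicate 1.

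PD1-low and naive cells were compared for what goes with antigen experience, though tissue and cell state differ together. Cd83, a marker of activated lymphocytes, rose by 5.95 ± 0.78 in PD1-low cells (adjusted p = 0.0478, n = 2 and 2). Il2rb, a subunit of the interleukin 2 receptor, rose by 2.97 ± 0.31 (adjusted p = 0.0152), and Nrp1, a surface receptor of regulatory T cells, rose by 4.06 ± 0.45 (adjusted p = 0.0208). Sik1, a salt-inducible kinase, rose by 4.24 ± 0.49, and Egln3, an oxygen-sensing hydroxylase, was at least 1.51-fold higher. Auts2 was at least 2.06-fold lower (adjusted p = 0.00243).

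In the regulatory T cell list, 1 of 14 measured genes rose, 9 adjusted over the list alone and 4 with the batch term (list higher in camera, adjusted p = 8.23e-16, and adjusted p = 0.206 with an estimated correlation). In the IL-2 and STAT5 response list, 1 of 16 measured genes rose, 5 adjusted over the list alone and 2 with the batch term (list higher in camera, adjusted p = 0.00183, and adjusted p = 0.523 with an estimated correlation). In the T cell receptor and costimulation response list, 0 of 24 measured genes passed the test in limma, while 12 were higher and 0 lower at an unadjusted p under 0.05, 12 and 0 passed adjusted over the list alone and 3 rose and 0 fell with the batch term (list higher in camera, adjusted p = 1.11e-13, and adjusted p = 0.262 with an estimated correlation). Jun differed by 3.59 ± 0.50 (adjusted p = 0.0658) and Fos by 4.46 ± 0.75 (adjusted p = 0.117). In the type I interferon response list, 0 of 18 measured genes passed the test in limma, while 3 were higher and 0 lower at an unadjusted p under 0.05, 1 and 0 passed adjusted over the list alone and 1 rose and 0 fell with the batch term (list higher in camera, adjusted p = 9.33e-05, and adjusted p = 0.523 with an estimated correlation). Mx1 differed by 2.68 ± 0.49 (adjusted p = 0.162). In the CD8, NK and gamma delta T cell list, 0 of 8 measured genes passed the test in limma, while 3 were higher and 0 lower at an unadjusted p under 0.05, 3 and 0 passed adjusted over the list alone and 0 rose and 0 fell with the batch term (list higher in camera, adjusted p = 3.10e-04, and adjusted p = 0.305 with an estimated correlation). Gzma differed by 2.34 ± 0.57 (adjusted p = 0.385) and Eomes by 3.72 ± 1.01 (adjusted p = 0.504). The B cell genes Cd79b and Cd74 differed by 4.70 ± 1.34 (adjusted p = 0.580) and 3.83 ± 1.16 (adjusted p = 0.697). In all, limma called 8 genes for this comparison, 7 higher and 1 lower in PD1-low cells, 17 without the displaced probe sets, and 56 with the batch term, 43 higher and 13 lower. The median of all genes shifted by 0.28, and by -0.04 with the batch term. Batch 2 alone held both groups, with a difference of 4.46 for Cd83. The count was 41 without PD1-low replicate 1, 0 without PD1-low replicate 2 (181 at an unadjusted p under 0.05 in limma) and 2 without naive replicate 1.

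Venus-high Tfh were set against PD1-low cells, the ends of the lymph node populations. Il4, a cytokine of Tfh and Th2 cells, was at least 112-fold higher in Venus-high Tfh (adjusted p = 6.41e-05, n = 3 and 2), and Il21 was at least 100-fold higher (adjusted p = 4.14e-05). Ccr7 was at least 303-fold lower (adjusted p = 5.55e-06), and S1pr1, the receptor for egress from lymph nodes, was at least 22.5-fold lower (adjusted p = 2.05e-04). Il2ra, the high-affinity subunit of the interleukin 2 receptor, was at least 135-fold lower (adjusted p = 0.00223).

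In the Tfh programme list, 15 of 22 measured genes rose, 15 adjusted over the list alone and 20 with the batch term (list higher in camera, adjusted p = 8.59e-16, and adjusted p = 0.0998 with an estimated correlation). Ascl2 was at least 155-fold higher and Cebpa at least 357-fold. In the T zone homing and egress receptor list, 8 of 10 measured genes fell, 8 adjusted over the list alone and 8 with the batch term (list lower in camera, adjusted p = 1.08e-08, and adjusted p = 0.0998 with an estimated correlation). Il7r fell by 6.26 ± 0.43 and Klf2, a transcription factor of quiescent T cells, was at least 40.3-fold lower. In the naive and quiescence list, 0 of 17 measured genes rose and 10 fell, 0 and 11 adjusted over the list alone, and 1 and 11 with the batch term (list lower in camera, adjusted p = 8.23e-10, and adjusted p = 0.0998 with an estimated correlation). Igfbp4 fell by 9.55 ± 0.99 and Dapl1 fell by 8.14 ± 1.09. In the cell cycle list, 15 of 31 measured genes rose, 22 adjusted over the list alone and 25 with the batch term (list higher in camera, adjusted p = 1.38e-13, and adjusted p = 0.224 with an estimated correlation). Cdk1 rose by 5.15 ± 0.74, Ccnb2 rose by 4.80 ± 0.66 and Tpx2 rose by 4.73 ± 0.61. In the IL-2 and STAT5 response list, 0 of 16 measured genes rose and 4 fell, 0 and 5 adjusted over the list alone, and 1 and 7 with the batch term (list lower in camera, adjusted p = 0.00203, and adjusted p = 0.450 with an estimated correlation). Socs2 was at least 37.5-fold lower and Cish at least 39.2-fold. In the glycolysis list, 8 of 15 measured genes rose and 1 fell, 10 and 2 adjusted over the list alone, and 11 and 2 with the batch term (list higher in camera, adjusted p = 1.70e-05, and adjusted p = 0.224 with an estimated correlation). Aldoc, an aldolase, was at least 25.4-fold higher, and Tpi1, triosephosphate isomerase, rose by 2.76 ± 0.32. In the inhibitory receptor list, 5 of 11 measured genes rose, 6 adjusted over the list alone and 7 with the batch term (list higher in camera, adjusted p = 3.83e-05, and adjusted p = 0.321 with an estimated correlation). Lag3 rose by 8.02 ± 0.70 and Cd160 rose by 5.18 ± 0.53. Without the gate gene Pdcd1, left out after seeing the data, 4 of 10 rose (camera, adjusted p = 8.86e-04, and adjusted p = 0.470 with an estimated correlation).

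In the CD8, NK and gamma delta T cell list, 1 of 8 measured genes rose and 3 fell, 1 and 4 adjusted over the list alone, and 1 and 3 with the batch term (list lower in camera, adjusted p = 0.0492, and adjusted p = 0.450 with an estimated correlation, and adjusted p = 0.0966 with the batch term). Klrd1 was at least 70.9-fold lower and Cd8b1 at least 2.80-fold, while Gzma rose by 2.52 ± 0.52. In the germinal centre B cell and plasma cell list, 3 of 5 measured genes rose, 3 adjusted over the list alone and 4 with the batch term (list higher in camera, adjusted p = 5.92e-06, and adjusted p = 0.0998 with an estimated correlation). Without the gate gene S1pr2, left out after seeing the data, 2 of 4 rose (camera, adjusted p = 3.67e-04, and adjusted p = 0.188 with an estimated correlation). In the B cell list, 1 of 8 measured genes rose and 1 fell, 1 and 2 adjusted over the list alone, and 2 and 2 with the batch term (camera, adjusted p = 0.982). Cd22 was at least 182-fold higher, while Cd72 fell by 5.003 ± 0.39. The myeloid gene Cd68 rose by 3.91 ± 0.37 (adjusted p = 2.08e-04), from 5.19 to 9.10. Gal was at least 275-fold higher, Padi4 at least 310-fold and Vdr at least 269-fold, while Pdlim4 was at least 96.0-fold lower, Dntt at least 98.2-fold and Itgb3 at least 164-fold. In all, limma called 1115 genes for this comparison, 627 higher and 488 lower in Venus-high Tfh, 1185 without the displaced probe sets, and 3428 with the batch term, 1881 higher and 1547 lower. The median of all genes shifted by -0.10, and by 0.01 with the batch term. Batches 2 and 3 held both groups, with differences of -9.33 and -9.50 for Ccr7 and 8.89 and 7.33 for Lag3. The count was 619 without PD1-low replicate 1 and 715 without PD1-low replicate 2.

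Against naive cells, Venus-high Tfh again differed in tissue as well as in state. Lag3, an inhibitory receptor, was at least 172-fold higher in Venus-high Tfh (adjusted p = 2.73e-05, n = 3 and 2), and Cxcr3, a chemokine receptor of effector T cells, was at least 68.4-fold higher (adjusted p = 0.00123). Ccr7 was at least 312-fold lower (adjusted p = 4.14e-06), and S1pr1 was at least 17.2-fold lower (adjusted p = 2.31e-04). Nusap1, a protein of the mitotic spindle, was at least 43.9-fold higher (adjusted p = 0.00342).

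In the Tfh programme list, 18 of 22 measured genes rose, 19 adjusted over the list alone and 20 with the batch term (list higher in camera, adjusted p = 1.04e-15, and adjusted p = 0.101 with an estimated correlation). Ascl2 was at least 155-fold higher and Il4 at least 112-fold. In the T zone homing and egress receptor list, 8 of 10 measured genes fell, 8 adjusted over the list alone and 9 with the batch term (list lower in camera, adjusted p = 1.07e-10, and adjusted p = 0.0943 with an estimated correlation). Il7r fell by 6.40 ± 0.43. In the cell cycle list, 20 of 31 measured genes rose, 24 adjusted over the list alone and 23 with the batch term (list higher in camera, adjusted p = 2.66e-12, and adjusted p = 0.243 with an estimated correlation). Tpx2 was at least 29.5-fold higher and Cdk1 at least 21.7-fold. In the inhibitory receptor list, 8 of 11 measured genes rose, 8 adjusted over the list alone and 8 with the batch term (list higher in camera, adjusted p = 2.76e-06, and adjusted p = 0.243 with an estimated correlation). Cd160 was at least 99.8-fold higher and Pdcd1lg2 at least 19.4-fold. Without the gate gene Pdcd1, left out after seeing the data, 7 of 10 rose (camera, adjusted p = 5.62e-05, and adjusted p = 0.303 with an estimated correlation). In the T cell receptor and costimulation response list, 10 of 24 measured genes rose and 0 fell, 12 and 0 adjusted over the list alone, and 15 and 2 with the batch term (list higher in camera, adjusted p = 1.53e-05, and adjusted p = 0.361 with an estimated correlation). Dusp4 was at least 34.9-fold higher and Irf8 at least 13.1-fold. In the inflammatory homing receptor list, 6 of 13 measured genes rose and 0 fell, 6 and 0 adjusted over the list alone, and 6 and 1 with the batch term (list higher in camera, adjusted p = 0.00694, and adjusted p = 0.423 with an estimated correlation). Cxcr6 was at least 70.8-fold higher. Without the gate gene Cd44, left out after seeing the data, 5 of 12 rose (camera, adjusted p = 0.0306, and adjusted p = 0.581 with an estimated correlation, and adjusted p = 0.0558 with the batch term). In the regulatory T cell list, 6 of 14 measured genes rose and 3 fell, 7 and 4 adjusted over the list alone, and 7 and 4 with the batch term (camera, adjusted p = 0.294). Ctla4 rose by 5.48 ± 0.99, while Gpr83 fell by 6.15 ± 0.63. The myeloid gene Cd68 was at least 17.1-fold higher (adjusted p = 3.60e-05). Egln3 was at least 235-fold higher, Cebpa at least 357-fold, Padi4 at least 310-fold and Vdr at least 269-fold. Igfbp4 fell by 10.09 ± 0.99, while Pdlim4 was at least 95.8-fold lower, Itgb3 at least 188-fold and Ampd1 at least 43.3-fold. In all, limma called 1356 genes for this comparison, 938 higher and 418 lower in Venus-high Tfh, 1433 without the displaced probe sets, and 4066 with the batch term, 2000 higher and 2066 lower. The median of all genes shifted by 0.18, and by -0.02 with the batch term. Batches 1 and 2 held both groups, with differences of -9.75 and -9.61 for Ccr7 and 10.04 and 9.87 for Lag3. The count was 853 without naive replicate 1 and 818 without naive replicate 2.

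The genes called between PD1-intermediate and PD1-low cells were then followed in the Tfh groups, on arrays outside that contrast. Of the 304 genes higher in PD1-intermediate cells, 50% were higher in Venus-high than in Venus-low Tfh, and of the 93 lower genes, 65.6% were lower. Over both sets 53.7% moved the same way. The median difference between the Tfh groups was -0.003 for the first set and -0.016 for the second. The shares therefore count the signs of many differences near 0. The first set lay lower in Venus-high Tfh than other genes did in camera at the preset correlation (p = 0.0218; p = 0.688 with an estimated correlation), it did not pass in fry, which tests it against no change, and the second set did not pass (camera, p = 0.189). The share was 44.8% without Venus-high replicate 3, 49.9% without Venus-low replicate 1 and 45.1% without Venus-low replicate 2, so that its direction rested on single arrays. With the batch term it was 52.3%, and the first set did not pass in camera.

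**Figure D3:**
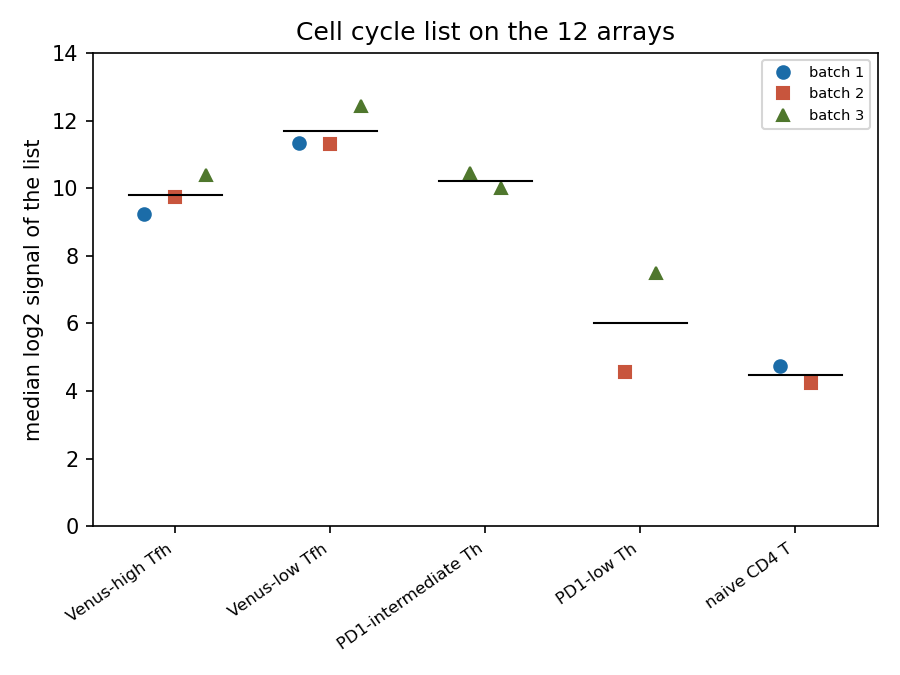
Median log2 signal of the 31 measured cell cycle genes on each of the 12 arrays by group, 1 point per array, with the batch as shape and colour and the group mean as a black line. The 3 Venus-low arrays sit at 11.3, 11.3 and 12.4, above the Venus-high array of the same batch at 9.24, 9.74 and 10.4.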

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

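The splits of the arrays and the correlation of paired probe sets over all probe sets were planned; every other test in this part was chosen after the result was seen. Some readings were also changed after their values were known. The paired probe set test, by its rule, would have counted against a change of whole transcripts, and was set aside as uninformative once probe sets were found out of place. The test of the amplification controls was first read as pointing to amplification and then left open, because control probe sets of batch 2 had lost their signal. A first test of sex had too weak a rule and was replaced by a pair of tests. The test of separate normalization was first read as arguing against it and then left open, the tests of other cell types in the gates were rewritten more than once, and B cells and CD8 T cells were first read as argued against.

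Signal was present in data that no comparison used. Of 2537 probe sets past the filter without a single gene symbol, displaced ones left out, 58 were higher in Venus-high Tfh than in naive cells in limma with the batch term and below log2 5 on both naive arrays.

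Arrays of 1 group differed between batches: their 8 pairs correlated across probe sets by 0.806 to 0.915, against 0.859 to 0.987 for different groups of 1 batch. Sex as the cause between batches 1 and 2, which differed in 4412 genes, stays open. Their Xist ranges overlapped, but within each shared group batch 2 read lower. In batches 1 and 2 Xist was 12.8 and 12.1 in Venus-high Tfh, 12.8 and 11.2 in Venus-low Tfh and 11.3 and 9.96 in naive cells. Overlapping ranges of pools therefore do not show an equal mix of sexes. Pool size between batches 1 and 3 is argued against, since their Tfh pools were all of 4 mice and they differed in 6473 genes. Paired probe sets of a gene correlated by -0.430 for the difference between batches 2 and 1, which displaced values set, against 0.857 for Venus-high Tfh minus PD1-low cells, and without these by 0.0864, against 0.865 (95% interval of the gap -0.83 to -0.73), and by 0.282 for batches 3 and 1 (gap -0.64 to -0.53), which argues against a change of whole transcripts as the main cause. Values held under another probe set of the gene may account for displaced probe sets of batch 2, but the correlations cannot decide it. The partner gave 0.715, against 0.184 for the own probe set, lowered in part by values at the floor, and -0.0817 for shuffled partners. The genes were chosen for an own probe set displaced down and a partner displaced up. A bright probe set of the same gene could follow its difference without any exchange. Whether names or signals moved was not tested. Open stay separate normalization, since joint quantile normalization moved the count between the Tfh groups from 130 to 412 genes without a batch term but cannot undo background and probe effects fitted in each batch, sex in batch 3, which holds every Xist-low array and differed from batch 2 in 6358 genes, amplification, with separate 3′ minus 5′ ranges of actin and Gapdh in 3 of 3 pairs of batches, and pool size in batch 2, where the naive arrays, both of 2 mice, correlated by 0.833 between batches 1 and 2 but are 1 pair.

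Of the regulatory T cell list, 3 of 14 genes fell in Venus-high against Venus-low Tfh, and of the CD8, NK and gamma delta T cell list 1 of 8, with adjusted p = 0.288 and adjusted p = 0.220 in camera with an estimated correlation. CD8 T cells in the Venus-low gate stay open, although the gate required CD4, since Cd8b1 read 2.55, 4.03 and 3.96 on the Venus-low and 2.51, 3.13 and 3.02 on the Venus-high arrays of batches 1, 2 and 3, near the floor. Cd8b1 read higher on the PD1-low arrays, at 6.35 and 6.62. NK and gamma delta T cells stay open too. Klrc1 reached 7.73, Klrd1 5.93 and Trgv4 7.51 on a Venus-low array. Klrc1 also read 6.72 and 6.31 on the PD1-intermediate arrays. Klrd1 was brighter on the naive arrays, at 9.45 and 9.73, and on the PD1-low arrays, at 10.8 and 11.5. Its level therefore does not single out NK cells here. Ncr1 and Cd8a, at 2.18 and 2.80 or less, were at the floor on all 12 arrays and decide nothing. A smaller share of Foxp3-expressing cells in the Venus-high gate may account for the regulatory genes, but cannot be told apart from a change within each cell on arrays of pooled cells: 7 of 14 measured genes of that list fell with the batch term and none rose, and 7 did not pass.

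Mef2b, a transcription factor of germinal centre B cells, was higher in Venus-high than in Venus-low Tfh. B cells carried over into the Venus-high gate cannot be told apart from expression by the Tfh cells, since the 7 B cell list genes with signal on a Tfh array, 1 displaced gene left out, went both ways with the batch term, with a median of 0.49. The 95% interval lay below 0 for 3 of them, Cd79b at -1.85, Cd74 at -2.22 and Cd72 at -1.81, and above 0 for 2, Ighm at 0.49 and Spib at 1.80, while Cd22 differed by 0.99 and Ebf1 by 0.52. Not all of these genes single out B cells here. Ighm read 12.2 to 13.7 on all 12 arrays and was highest on naive array 1. Cd72 was brightest on the PD1-low and naive arrays, at 10.9 to 11.6. Ebf1 read 5.37 to 7.54 in batches 1 and 2 but at most 2.74 in batch 3, so its level went with the batch. Cd79b reached at most 3.99 on a Venus-high array, and the gates excluded cells of other lineages. Of the 18 B cell list genes with a named probe set, 10 stayed below log2 5 on every array, Cd79a and Ms4a1 among them. No array held B cells for reference, so a silent probe set cannot be told from absent cells.

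The 6 Tfh arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 130 genes in limma, 1 split, the real one, gave as many, and the highest other gave 2. Among the 4 splits that part all 3 pairs, the real one gave 1671 genes with the batch term, and each other gave 0, with at most 254 at an unadjusted p under 0.05.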

How the results depend on the processing

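Alternatives with batch or displaced probe sets, or with the replicate block on 6 arrays, were chosen after seeing the data. No named gene turned around: of 6960 values under alternatives, 6110 kept direction and side of the threshold, 501 lost the call, 298 gained it and 51 without a call changed sign. Of 130 counts of genes, 66 moved by more than 1.5 times, as did 23 of 59 with the batch term and 14 of 65 counts of lists. Unless a setting itself removes arrays or genes, the cause was not tested. A lone array left in a group was assumed to vary like the other groups, the pool size could not be a term for naive cells, and signal near background limits dim genes. Dropping the filter gave 20 genes and 18 lists for PD1-low against naive. The carry-over share, which was not itself tested, was then 58.9%, and neither gene set passed in camera. With the filter, only the genes higher in PD1-intermediate cells had passed, and they lay lower in Venus-high Tfh, against a carry-over. Filtering at log2 7 gave 5 genes for PD1-low against naive. Joint quantile normalization gave 412 genes for Venus-high against Venus-low, 146 for Venus-low against PD1-intermediate, 638 for PD1-intermediate against PD1-low, 37 for PD1-low against naive, 1769 for Venus-high against PD1-low. Centring on array medians gave 324 genes for Venus-high against Venus-low, 127 for Venus-low against PD1-intermediate, 17 for PD1-low against naive. A robust variance trend gave 21 genes for Venus-low against PD1-intermediate. Fitting the 2 groups alone gave 4 genes for Venus-high against Venus-low, 2 for Venus-low against PD1-intermediate, 95 for PD1-intermediate against PD1-low, 0 for PD1-low against naive, 431 for Venus-high against PD1-low, 681 for Venus-high against naive, an S1pr2 difference of 2.64 (adjusted p = 0.0849), the 0 standing beside 241 at an unadjusted p under 0.05. The replicate block gave 262 genes for Venus-high against Venus-low, 2757 for Venus-low against PD1-intermediate, 692 for PD1-intermediate against PD1-low, 25 for PD1-low against naive, 2564 for Venus-high against PD1-low, 5 lists for Venus-low against PD1-intermediate. The replicate numbers of PD1-intermediate and PD1-low arrays did not follow the batches, so the replicate block joined arrays of different batches. A term for pool size gave 15 genes for Venus-low against PD1-intermediate. Array weights, which did not converge and are doubtful, gave 2602 genes for Venus-high against Venus-low, 6873 for Venus-low against PD1-intermediate, 2345 for Venus-high against naive. The mean of probe sets gave 2 genes for PD1-low against naive, an S1pr2 difference of 2.34 (adjusted p = 0.0631). The batch term gave 1671 genes for Venus-high against Venus-low, 631 for Venus-low against PD1-intermediate and 1266 for PD1-intermediate against PD1-low. It gave 56 for PD1-low against naive, 3428 for Venus-high against PD1-low and 4066 for Venus-high against naive. With it the carry-over share was 52.3%, and neither gene set passed in camera. Leaving out displaced probe sets gave 17 genes for PD1-low against naive. The batch term without displaced probe sets gave 1718 genes for Venus-high against Venus-low, 646 for Venus-low against PD1-intermediate, 1320 for PD1-intermediate against PD1-low, 59 for PD1-low against naive, 3499 for Venus-high against PD1-low, 4100 for Venus-high against naive. Batch as a random block gave 1807 genes for Venus-high against Venus-low, 900 for Venus-low against PD1-intermediate, 1419 for PD1-intermediate against PD1-low, 104 for PD1-low against naive, 3452 for Venus-high against PD1-low, 4058 for Venus-high against naive. The replicate block on the 6 Tfh arrays gave 1001 genes for Venus-high against Venus-low. With the batch term, no filter gave 249 genes for Venus-low against PD1-intermediate. With the batch term, a robust variance trend gave 87 genes for PD1-low against naive. With the batch term, leaving out batch 2 gave 1095 genes for Venus-high against Venus-low, 344 for Venus-low against PD1-intermediate, 452 for PD1-low against naive. Camera with an estimated correlation gave 0 lists for each comparison, and neither carry-over set passed, at an unchanged share of 53.7%. The rotation test fry gave 5 lists for Venus-high against Venus-low and 0 for Venus-low against PD1-intermediate. The 0 stood beside 2 lists at an unadjusted p under 0.05. It gave 6 lists for PD1-intermediate against PD1-low and 4 for PD1-low against naive. Neither carry-over set passed in it, at the same share of 53.7%. With the batch term neither carry-over set passed in fry, at a share of 52.3%. With each array left out in turn, 33 to 152 genes for Venus-high against Venus-low, 5 to 40 for Venus-low against PD1-intermediate, 137 to 385 for PD1-intermediate against PD1-low, 0 to 41 for PD1-low against naive, 619 to 1021 for Venus-high against PD1-low, 818 to 1295 for Venus-high against naive were called. The same with the batch term gave 728 to 1117 genes for Venus-high against Venus-low, 5 to 380 for Venus-low against PD1-intermediate, 453 to 830 for PD1-intermediate against PD1-low, 28 to 828 for PD1-low against naive, 2092 to 3174 for Venus-high against PD1-low. Lists ranged from 5 to 8 for Venus-low against PD1-intermediate. The S1pr2 difference then ranged from 2.45 to 2.86, and the carry-over from 44.8 to 60.4%, with 49.9% and 45.1% without Venus-low replicates 1 and 2.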

Other observations

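Venus-high Tfh and PD1-intermediate cells were compared for the cell cycle list alone, a comparison chosen after seeing the data. Of the 31 genes, 0 rose and 0 fell in limma with the batch term, 3 having an unadjusted p under 0.05, and the median difference was 0.05. Without the batch term the median difference was -0.62, with 2 genes at an unadjusted p under 0.05. The list did not pass in camera in either fit, and a p that misses the threshold does not show that the levels were equal.

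For Venus-high against Venus-low Tfh, further lists were as follows. In the inflammatory homing receptor list, 0 of 13 measured genes passed the test in limma, while 0 were higher and 3 lower at an unadjusted p under 0.05, 0 and 2 passed adjusted over the list alone and 0 rose and 3 fell with the batch term (list lower in camera, adjusted p = 0.00958, and adjusted p = 0.452 with an estimated correlation). In the type I interferon response list, 0 of 18 measured genes passed the test in limma, while 0 were higher and 0 lower at an unadjusted p under 0.05, 0 and 0 passed adjusted over the list alone and 0 rose and 1 fell with the batch term (camera, adjusted p = 0.700). In the oxidative phosphorylation list, 0 of 24 measured genes passed the test in limma, while 0 were higher and 1 lower at an unadjusted p under 0.05, 0 and 0 passed adjusted over the list alone and 0 rose and 2 fell with the batch term (camera, adjusted p = 0.0951; list lower with the batch term, adjusted p = 0.0225, and adjusted p = 0.227 with an estimated correlation). In the apoptosis list, 0 of 14 measured genes passed the test in limma, while 0 were higher and 0 lower at an unadjusted p under 0.05, 0 and 0 passed adjusted over the list alone and 0 rose and 1 fell with the batch term (camera, adjusted p = 0.661).

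Further lists passed in camera in the other comparisons, each losing its call with an estimated correlation, and are given as adjusted p with the genes called in limma. In Venus-low Tfh against PD1-intermediate cells, the T zone homing and egress receptor list was lower (adjusted p = 0.00754, and adjusted p = 0.432 with an estimated correlation), with 0 of 10 genes higher and 0 lower and the inhibitory receptor list was higher (adjusted p = 0.0292, and adjusted p = 0.755 with an estimated correlation, and adjusted p = 0.113 without Pdcd1), with 0 of 11 genes higher and 0 lower. In PD1-intermediate against PD1-low cells, the T zone homing and egress receptor list was lower (adjusted p = 1.34e-04, and adjusted p = 0.230 with an estimated correlation), with 1 of 10 genes, Gpr183, higher and 0 lower, the Th1 list was higher (adjusted p = 0.0110, and adjusted p = 0.476 with an estimated correlation), with 1 of 13 genes higher and 0 lower and the glycolysis list was higher (adjusted p = 0.0148, and adjusted p = 0.476 with an estimated correlation), with 0 of 15 genes higher and 0 lower. In PD1-low against naive cells, the Tfh programme list was higher (adjusted p = 0.00303, and adjusted p = 0.639 with an estimated correlation), with 0 of 22 genes higher and 0 lower, the inflammatory homing receptor list was higher (adjusted p = 3.10e-04, and adjusted p = 0.404 with an estimated correlation, and adjusted p = 0.00635 without Cd44), with 0 of 13 genes higher and 0 lower, the Th17 list was higher (adjusted p = 5.31e-04, and adjusted p = 0.371 with an estimated correlation), with 0 of 7 genes higher and 0 lower and the inhibitory receptor list was higher (adjusted p = 1.29e-04, and adjusted p = 0.404 with an estimated correlation, and adjusted p = 6.73e-04 without Pdcd1), with 0 of 11 genes higher and 0 lower. In Venus-high Tfh against PD1-low cells, the Th17 list was higher (adjusted p = 0.0135, and adjusted p = 0.440 with an estimated correlation, and adjusted p = 0.0539 with the batch term), with 4 of 7 genes higher and 0 lower. In Venus-high Tfh against naive cells, the Th17 list was higher (adjusted p = 5.32e-04, and adjusted p = 0.243 with an estimated correlation), with 5 of 7 genes higher and 0 lower, the naive and quiescence list was lower (adjusted p = 4.46e-11, and adjusted p = 0.0943 with an estimated correlation), with 0 of 17 genes higher and 10 lower, the glycolysis list was higher (adjusted p = 1.57e-04, and adjusted p = 0.252 with an estimated correlation), with 10 of 15 genes higher and 0 lower and the germinal centre B cell and plasma cell list was higher (adjusted p = 2.07e-05, and adjusted p = 0.0943 with an estimated correlation, and adjusted p = 7.88e-04 without S1pr2), with 3 of 5 genes higher and 0 lower. At an unadjusted p under 0.05 in limma, the T zone homing and egress receptor and inhibitory receptor lists of the comparison of Venus-low Tfh against PD1-intermediate cells held 0 and 1 higher and 4 and 0 lower genes. At an unadjusted p under 0.05 in limma, the glycolysis list of the comparison of PD1-intermediate against PD1-low cells held 5 higher and 0 lower genes. At an unadjusted p under 0.05 in limma, the Tfh programme, inflammatory homing receptor, Th17 and inhibitory receptor lists of the comparison of PD1-low against naive cells held 1, 5, 4 and 5 higher and 0, 0, 0 and 0 lower genes.

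Of markers of other cell types, the 7 erythrocyte and platelet genes with a named probe set stayed below log2 5 on every array. So did 17 of 22 myeloid and dendritic cell genes, 10 of 13 stromal genes and 10 of 18 B cell genes. The counts were 4 of 9 for germinal centre B and plasma cells and 6 of 14 for CD8, NK and gamma delta T cells. Of the myeloid genes above that level, Cd68 read 8.83 to 9.26 on Venus-high and 8.08 to 8.79 on Venus-low arrays, against 3.89 and 4.06 on the naive arrays, and Mpeg1 reached 7.03 on Venus-high array 3 alone. Cst3 read 10.6 to 13.2 on all 12 arrays, naive ones included, and S100a9 was highest on naive array 1, at 6.30.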
